A study of Carassius auratus with 5 samples.

How the data were processed

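Telencephalon RNA of female goldfish exposed to fadrozole was hybridized on 5 cDNA arrays, each with 1 independent group of exposed fish (Cy3) against 1 common pool of unexposed fish (Cy5), per the labels. The arrays are replicates 1 to 5, from slides 4, 14, 22, 33 and 44. Per the file headers, the spot intensity and local background values are linear scanner units from a 2-channel scan with adaptive quantification, not background subtracted and not corrected for crosstalk. The deposited files give 1 intensity per spot and channel and do not name it as a mean or a median, so that the median foreground planned for the test was replaced by this value. The authors also deposited processed log2-like values, 1 per spot, whose log base and scaling are not stated. Set against log2 ratios made from the scanner values by plain background subtraction and loess, they had correlations across spots of -0.996 to -1.00, where spots are not independent replicates, with slopes of -0.73 to -0.81. They therefore give control over fadrozole, and their sign was turned for the comparison. Each of the authors' columns has a mean of -0.0046. Gene names are the descriptions the files pair with the clones, and no genome positions were used.

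The background was corrected by the normexp method with an offset of 50 and each array was normalized by a loess curve over all clone spots with a span of 0.3, in limma 3.58.1 (R 4.3.3, statmod 1.5.0). Control and empty spots and spots that the scanner software marked as ignored (0 to 29 per array) had no weight, and the 2 spots of a clone were averaged. A clone was tested when its intensity exceeded the local background by 2 background SDs, in at least 1 channel and at least 0.5 of its usable spots, on at least 3 arrays, which left 8078 of 8099 clones, 3325 of them with a gene description. The mean log2 ratio of fadrozole over control was tested against 0 by limma's moderated test, two-sided, with Benjamini-Hochberg adjustment over the tested clones and a threshold of 0.05. The test had 4 residual and 5.24 prior degrees of freedom.

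The tests, the alternatives and 23 gene lists, written as word patterns for the tissue, the treatment and cells that a dissection could include, were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, two-sided, with adjustment over the 23 lists, and again with an estimated correlation and with fry, which tests whether a list moves without comparing it with other genes. The rule for named genes took the 10 described genes with the largest called ratios and 1 sign on all arrays in each direction, with 1 clone per gene name, the one with the smallest p, up to 4 called members of each list by smallest p (up to 2 uncalled where there were 0), and a fixed set that included aromatase, steroid receptors, GnRH, isotocin and GFAP. Patterns that missed a member or matched a wrong word were corrected from the spot names alone after the data were seen, and the lists as first written are the ones reported.

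The alternatives fixed at that point were no or plain background subtraction, median centering, print-tip loess, scale normalization, a stricter or no filter, ignored spots kept, the authors' values, an intensity trend with robust empirical Bayes, array weights, a minimum fold of 1.2, replicate spots kept apart, a plain one-sample test, and each array left out. Alternatives chosen after the data were seen were centering each source plate with at least 20 clones on its median, leaving out plates 02 and 04, the day of image quantification as a random block, corrected lists, and clones of 1 gene averaged. The source plate was read from the first characters of the clone name. All arrays were scanned on 1 day and quantified on 2 days, replicate 1 apart from the other 4, so that a scan day block could not be fitted.

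The pipeline was tested on 5 simulated arrays with 8078 clones. There limma called 52 of 100 clones made to change 1.5-fold, with a median log2 size of 0.38, and 83 of 100 made to change 2-fold, with a median of 0.71. It called 6 of 7878 clones that were not changed, and camera called the list shifted by 0.2 and 0 of 10 others. The simulated fadrozole channel was built from the control channel, and the spread was drawn for each clone apart, without a shift of source plates. The simulation therefore does not show how the tests behave with a dim fadrozole channel, a plate shift or correlated clones. Signs of the 5 arrays were turned in all 16 ways that count a split and its mirror once, and the number of calls was counted for each.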

Results

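RNA from the telencephalon of sexually mature female goldfish was measured on 5 two-color cDNA arrays. On each array, 1 independent group of fish exposed to waterborne fadrozole at 50 µg/L, labeled with Cy3, was hybridized against 1 common pool of unexposed fish, labeled with Cy5. Fadrozole is an inhibitor of aromatase, the enzyme that makes estrogens from androgens and is abundant in the fish forebrain. Each array held 17328 spots for 8099 cDNA clones spotted in duplicate, of which 3335 carried a gene description. The median spot intensity ran from 62.9 to 96.4 in the control channel and from 122 to 386 in the fadrozole channel. The control channel stood above its local background at 79.3% to 90.7% of the spots and the fadrozole channel at 22.7% to 64.8%. Empty spots had median intensities of 0 to 52.3 in the control channel and 98.0 to 310 in the fadrozole channel. Above background here and below refers to the local background, and does not by itself show a signal above that of an empty spot. The number of arrays limits the precision of every value below.

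The comparison asks which transcripts of the telencephalon differ after exposure to an aromatase inhibitor. Values are mean log2 ratios of fadrozole over control ± SD over the 5 arrays, so that a negative value means a lower signal in exposed fish. Of the 41 clones with a gene description that were called lower, 9 were on the list of neuronal cytoskeleton and synapse genes, 8 of them on source plates 02 and 04. The lowest of the 41 was calm1b (calmodulin, a calcium sensor, clone 02k06) at -0.83 ± 0.23, which is 1.78-fold lower. Others, of varied function, were an aldolase C clone (a glycolytic enzyme, 02n15) at -0.72 ± 0.26, odc1 (ornithine decarboxylase, which starts polyamine synthesis, 02g18) at -0.70 ± 0.22, uchL1 (a neuronal ubiquitin hydrolase, 02i06) at -0.69 ± 0.33 and tubb2 (beta tubulin, 02d05) at -0.68 ± 0.16. The described clones called higher were led by NELF-E (a subunit of a factor that pauses transcription, 51g16) at 0.66 ± 0.22 and intestinal fatty acid-binding protein (24k10) at 0.64 ± 0.17. All but 3 of the 130 lower calls came from plates 02 and 04, 2 of the plates that the array was printed from.

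In all, limma called 164 of 8078 tested clones at an adjusted p under 0.05, 34 higher and 130 lower in the fadrozole channel. Each of the 164 had 1 sign on all 5 arrays, and 15 of the higher and 41 of the lower calls carried a gene description. At least 1.5-fold was reached by 6 higher and 52 lower clones, and 2-fold by 0. At an unadjusted p under 0.05 there were 1159 clones, 508 higher and 651 lower, where 403.9 would arise by chance.

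**Figure D1:**
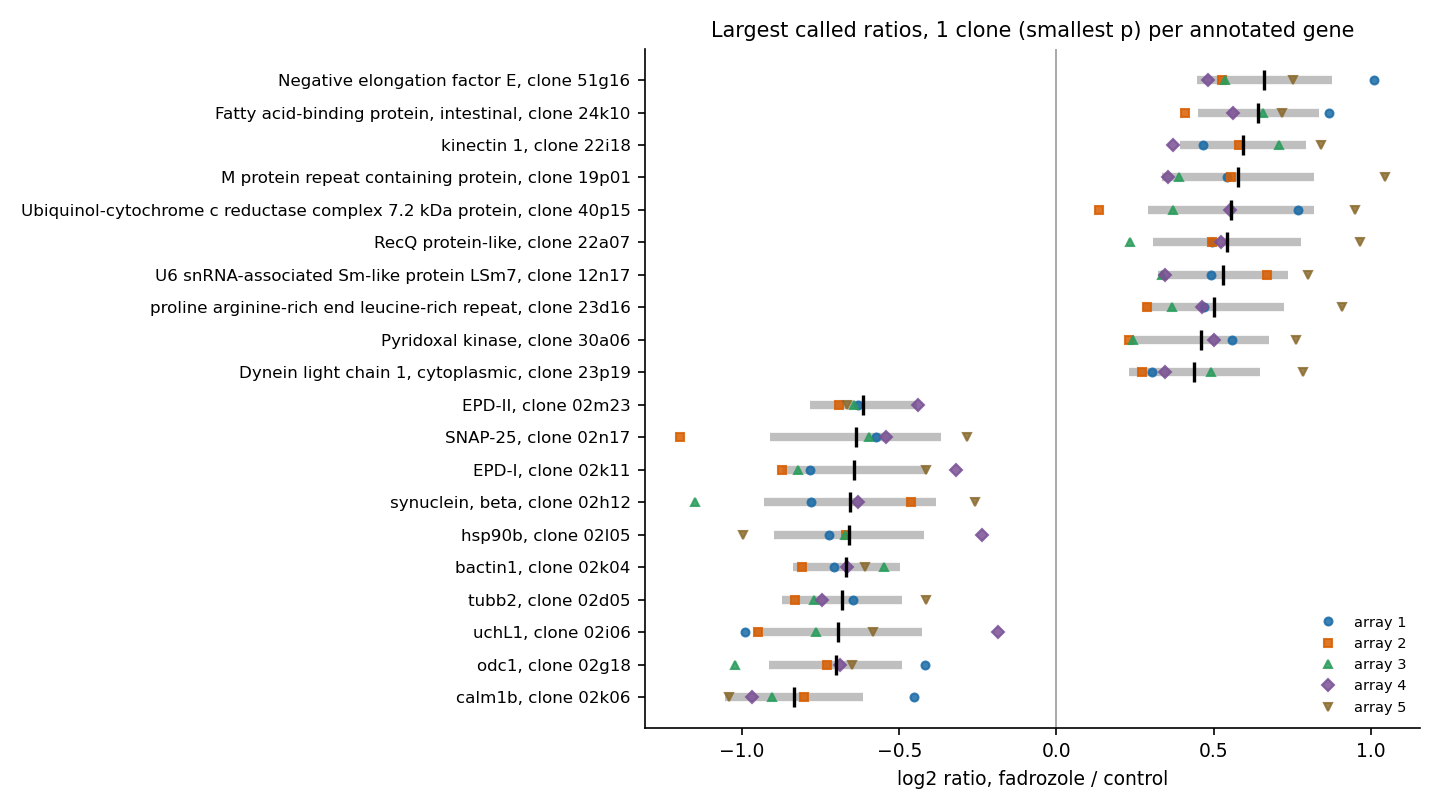
Log2 ratio of fadrozole over control (horizontal axis) for 10 described genes with large called ratios in each direction, chosen by size after taking the clone with the smallest p for each gene (for aldolase C, 02m03 at -0.57, which leaves it out); markers are the 5 arrays, black ticks their mean and gray bars the 95% confidence interval of the limma fit. All 5 arrays lie on 1 side of 0 for each clone, and the 10 lower clones all come from source plate 02.

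With each gene taken at its clone of smallest p, which places aldolase C at -0.57 (02m03), the other lower clones among the 10 largest were beta actin 1 (cytoskeleton, 02k04) at -0.67 ± 0.10, hsp90b (a chaperone, 02l05) at -0.66 ± 0.27 and a clone similar to beta synuclein (a presynaptic protein, 02h12) at -0.66 ± 0.34. EPD-I (02k11) stood at -0.64 ± 0.26, SNAP-25 (a protein of synaptic vesicle fusion, 02n17) at -0.64 ± 0.34 and EPD-II (02m23) at -0.61 ± 0.10. Their adjusted p values lay between 0.0152 for beta actin 1 and 0.0374 for SNAP-25. The fadrozole channel of uchL1 and hsp90b stood above background on 2 arrays each. Of the 3 lower calls on other plates, which are named after their values were seen, Calmodulin A (27c21) was at -0.45 ± 0.09, F-actin capping protein beta subunit (29d19) at -0.44 ± 0.16 and an unclassifiable EST (21d14) at -0.48 ± 0.07.

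Plates 02 and 04 held 127 of the 130 lower calls (97.7%), 94 on plate 02 and 33 on plate 04, and 768 of the tested clones (9.51%). The median of plate 02 was -0.35 ± 0.15 and that of plate 04 was -0.20 ± 0.08, against -0.04 ± 0.04 for plate 03. For 30 genes with clones both on these plates and elsewhere, the clones on the plates averaged -0.36 and the others -0.07 ± 0.03. The difference of -0.29 ± 0.15 was negative for 28 of the 30 genes. Plate 04 held 0 clones with a gene description, so that this comparison bears on plate 02 and does not test plate 04. Beta actin averaged -0.54 over 6 clones on the plates and -0.19 over 8 clones elsewhere, and an actin clone (01m15), named after its values were seen, was called higher at 0.40 ± 0.13. With the median of each plate set to 0, an alternative chosen after seeing the data, limma called 0 clones (smallest adjusted p = 0.0868, 910 at an unadjusted p under 0.05). Without the 2 plates it also called 0 (smallest adjusted p = 0.0724, 741 at an unadjusted p under 0.05).

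**Figure D2:**
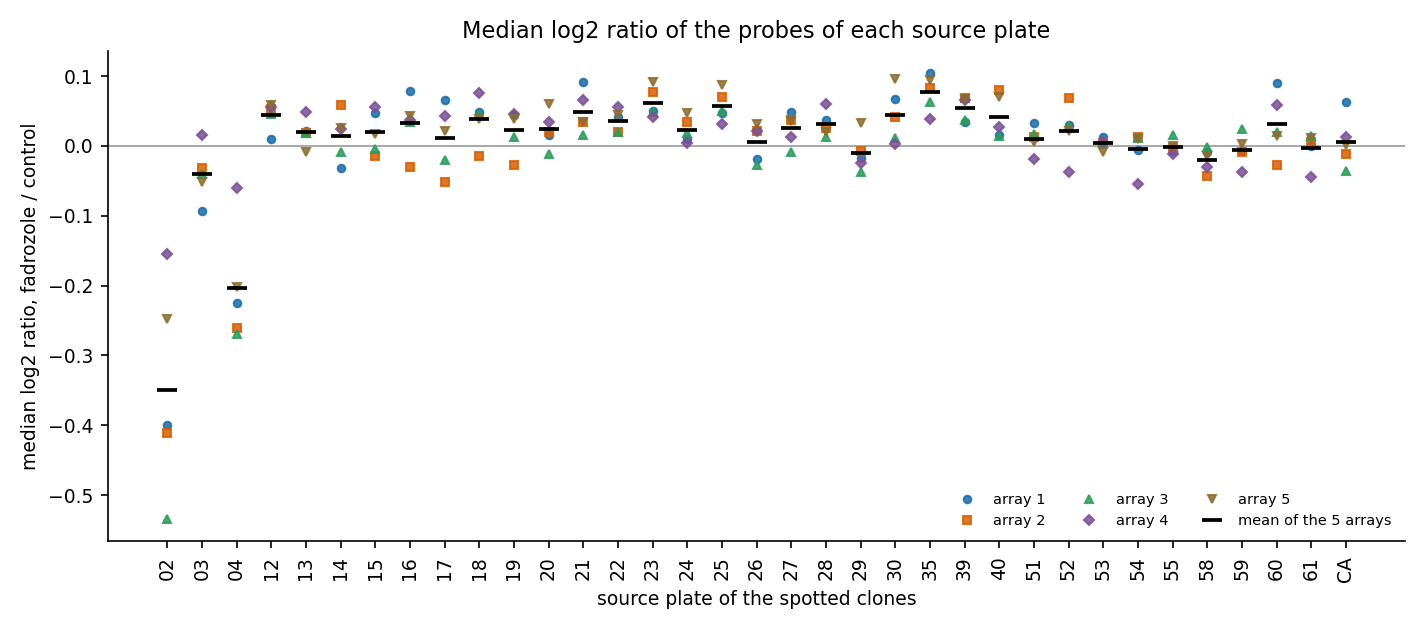
Median log2 ratio of fadrozole over control (vertical axis) of the clones of each source plate (horizontal axis); markers are the 5 arrays and black bars their mean. Plate 02 lies at -0.35 and plate 04 at -0.20, with plate 03 at -0.04.

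**Figure D3:**
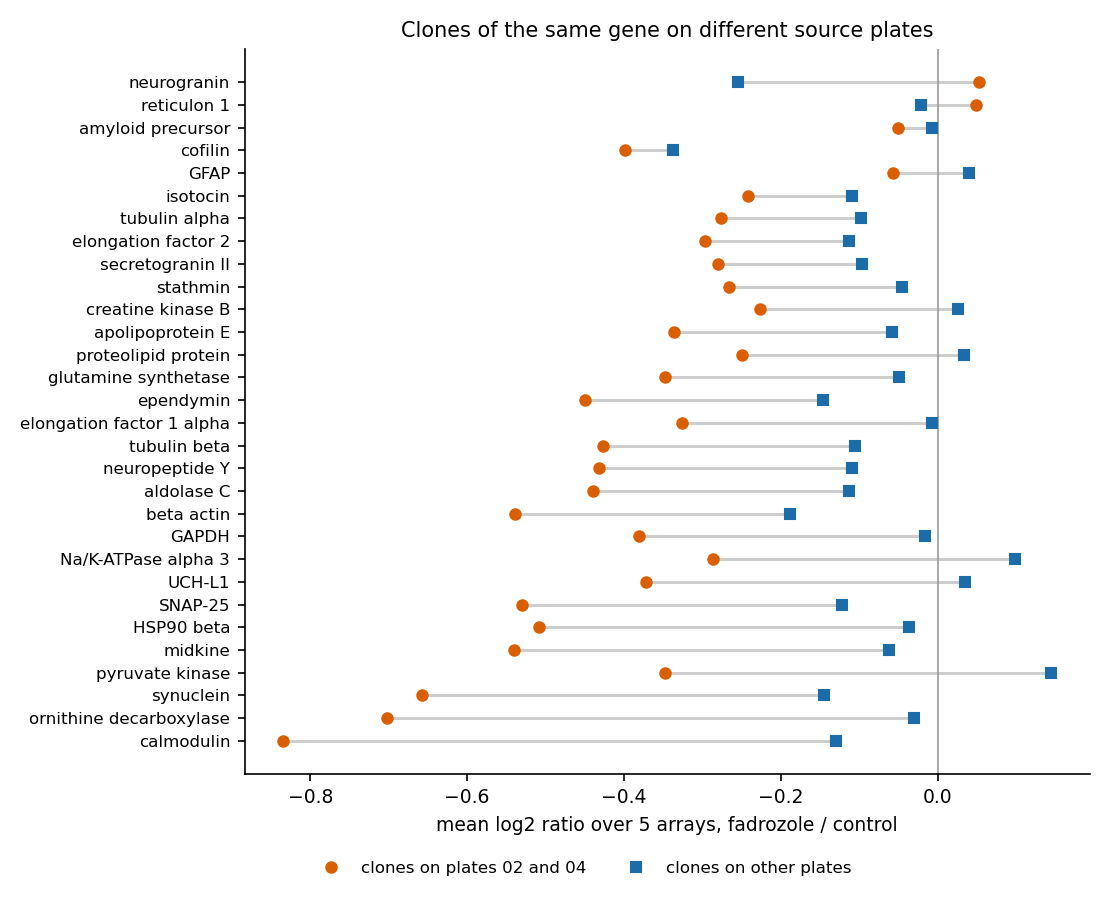
Mean log2 ratio of fadrozole over control over the 5 arrays (horizontal axis) for 30 genes, with clones on plates 02 and 04 as circles and clones on other plates as squares. The circle lies below the square for 28 of the 30 genes. Plate 04 holds 0 clones with a gene description.

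Among the gene lists chosen before the data were examined, the neuronal cytoskeleton and synapse list fell, with a mean of -0.11 ± 0.02 over 139 clones and below 0 on 5 of 5 arrays (camera adjusted p = 5.01e-05, and adjusted p = 0.0489 with an estimated correlation). The correlation estimated for these 139 clones was -0.007, below the preset 0.01, so that a larger correlation does not account for the higher p. Of these clones 0 were called higher and 9 lower (11 adjusted over the list alone), 8 of the 9 on plates 02 and 04. Without those plates its mean was -0.07 ± 0.02 over 125 clones, again below 0 on 5 of 5 arrays (adjusted p = 9.17e-06, and adjusted p = 0.0364 with an estimated correlation). With each plate centered the adjusted p was 0.000154, and 0.0527 with an estimated correlation, and over 26 alternatives it ran from 9.17e-06 to 0.0527. Outside the 2 plates, 31 clones with calmodulin in their description averaged -0.12 ± 0.06, 38 tubulin clones -0.08 ± 0.04, 7 SNAP-25 clones -0.12 ± 0.07 and 4 synuclein clones -0.15 ± 0.09, and these means stayed below 0 under 7 other ways of scaling the arrays. Stathmin, a regulator of microtubules, averaged -0.05 ± 0.13 over 10 clones there, below 0 on 4 of 5 arrays, and 0.00 with background not subtracted. These 5 families hold 103 of the 139 clones, and the other 35 clones outside the plates averaged 0.00 ± 0.07, below 0 on 3 of 5 arrays, with means between -0.02 and 0.01 under the 7 other scalings. The families were picked after the values were seen, so that the split describes where the fall was seen and does not test it. Over the 5 arrays the mean of the 35 other clones ran from -0.06 to 0.11.

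The radial glia and astroglia list fell to a mean of -0.17 ± 0.04 over 43 clones, below 0 on 5 of 5 arrays (adjusted p = 5.01e-05, and adjusted p = 0.0596 with an estimated correlation). Its 5 called clones (11 adjusted over the list alone), all lower, were aldolase C, a glycolytic enzyme of brain that is also on the glycolysis list, and all lay on plate 02. The lowest of them, 02n15, was at -0.72 ± 0.26. Aldolase C averaged -0.44 ± 0.14 over 13 clones on plates 02 and 04 and -0.11 ± 0.05 over 9 clones elsewhere. The 21 other clones of the list averaged -0.02 ± 0.02. Among them the 8 glutamine synthetase clones, with 0 called, averaged -0.12 ± 0.09, at -0.35 ± 0.35 for the 2 on plates 02 and 04 and -0.05 ± 0.06 for the 6 elsewhere. With each plate centered the adjusted p of the list was 0.43, within a range of 6.35e-06 to 0.832 over its alternatives.

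The glycolysis list fell to a mean of -0.12 ± 0.05 over 81 clones, below 0 on 5 of 5 arrays (adjusted p = 9.48e-05, and adjusted p = 0.126 with an estimated correlation). Of its clones 0 were called higher and 6 lower (15 adjusted over the list alone), 5 of them aldolase C and 1 GAPDH, and all 6 lay on plates 02 and 04. Outside the 2 plates, the 52 clones other than aldolase C averaged -0.01 ± 0.03. With each plate centered the adjusted p was 0.0425, and 0.237 with an estimated correlation, and without the 2 plates it was 0.105. Its range over the alternatives was 3.2e-05 to 0.457.

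Ribosomal proteins, the building parts of the ribosome, rose to a mean of 0.06 ± 0.05 over 133 clones, above 0 on 5 of 5 arrays (adjusted p = 0.0111, and adjusted p = 0.297 with an estimated correlation). Only 40S ribosomal protein S7 (39p04), at 0.42 ± 0.11, was called (1 adjusted over the list alone). The 57 small subunit clones averaged 0.07 ± 0.04, the 55 large subunit clones 0.09 ± 0.08 and the 18 mitochondrial ribosomal clones 0.00 ± 0.03, the last at -0.11 with plain background subtraction, -0.07 in the authors' values and -0.06 with background not subtracted. With each plate centered the adjusted p was 0.697, and without plates 02 and 04, which hold none of these clones but enter the comparison with other genes, it was 0.114. It was 0.144 with fry, 0.0681 with median centering and 0.0781 without replicate 2, and over the alternatives it ran from 0.00216 to 0.827.

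The pituitary hormone list, a marker of tissue from outside the telencephalon, had a mean of -0.22 ± 0.07 over 7 clones (adjusted p = 0.0125, and adjusted p = 0.211 with an estimated correlation). Its 2 called clones, 02p05 at -0.51 ± 0.16 and 02d23 at -0.37 ± 0.09, had matched letters in comments on the clone that name no hormone (4 lower adjusted over the list alone). With such matches dropped, 3 clones were left and the adjusted p was 0.11, and with each plate centered the mean was 0.03. Its adjusted p ran from 0.00794 to 0.882 over the alternatives. The endothelium and meninges list had a mean of 0.13 ± 0.08 over 8 clones with 0 called (adjusted p = 0.0427, and adjusted p = 0.297 with an estimated correlation). Collagenase 3 (22c20), a matrix protease, was at 0.37 ± 0.23 and passed only when adjusted over the list alone (1 higher). Tripartite motif protein 46 (25h05), which had matched the word fibronectin in its name, was at 0.20 ± 0.25. With wrong matches dropped the adjusted p was 0.549, and without replicates 2, 4 or 5 it was 0.0781, 0.0837 and 0.0999, within a range of 0.0193 to 0.688.

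Among the higher clones, kinectin 1 (an anchor of the motor protein kinesin, 22i18) was at 0.59 ± 0.19 and XE304 (19p01) at 0.58 ± 0.28. Ubiquinol-cytochrome c reductase (respiratory chain, 40p15) was at 0.56 ± 0.32 and a RecQ-like protein (a DNA helicase family, 22a07) at 0.54 ± 0.26. LSm7 (an RNA-binding protein of the spliceosome, 12n17) was at 0.53 ± 0.20 and a clone described as a proline arginine-rich end leucine-rich repeat protein (23d16) at 0.50 ± 0.24. Pyridoxal kinase (which activates vitamin B6, 30a06) was at 0.46 ± 0.22 and dynein light chain 1 (23p19) at 0.44 ± 0.21. Of the 34 higher calls, 33 lay outside plates 02 and 04. The exception, an undescribed clone (04m02) named after its values were seen, was at 0.54 ± 0.23. Higher calls too depended on these plates. Limma called 0 clones higher without plates 02 and 04 (smallest adjusted p = 0.0724) and 0 with each plate centered (smallest adjusted p = 0.0868).

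Among neuropeptides and their processing, the mean was -0.05 ± 0.08 over 44 clones (adjusted p = 0.0836), with 0 clones called higher and 3 lower (4 adjusted over the list alone), all on plate 02. These were PACAP (a peptide that raises cyclic AMP, 02g07) at -0.48 ± 0.14, secretogranin II (a granule protein and precursor of secretoneurin, 02j04) at -0.48 ± 0.20 and isotocin neurophysin (the fish counterpart of oxytocin, 02e11) at -0.56 ± 0.32. With each plate centered the mean of this list was 0.08, and over its 28 clones outside plates 02 and 04 it was 0.05 ± 0.10, against -0.24 on them. Its adjusted p was 0.0284 without replicate 4 and 0.0266 with corrected members, within a range of 0.0266 to 0.864. The GABA and glutamate list had a mean of -0.06 ± 0.05 over 53 clones with 0 called (adjusted p = 0.178), GABA-A beta 4 (02h18) being at -0.36 ± 0.16 and a GABA symporter clone (02f14) at -0.45 ± 0.27. Both lie on plate 02 and stood at -0.01 and -0.10 with each plate centered. The mean of the GABA and glutamate list was then 0.02, and -0.02 ± 0.02 over its 41 clones outside plates 02 and 04. In the monoamine list (16 clones, mean -0.06 ± 0.03, adjusted p = 0.568), 1 clone was called lower, HMP19 (02m16) at -0.43 ± 0.15, its fadrozole channel above background on 1 of 5 arrays. It is a neuronal vesicle protein rather than an enzyme or receptor of monoamines. With each plate centered, HMP19 stood at -0.08 and the mean of the monoamine list at 0.02. The activin, inhibin, BMP and TGF-beta list (12 clones, mean 0.11 ± 0.15, adjusted p = 0.62) and the steroid synthesis and sex steroid receptor list (13 clones, mean 0.02 ± 0.07, adjusted p = 0.62) had 0 calls. The steroid list as first written held 1 clone of plates 02 and 04, esr1 at -0.21, and left out ER beta1 and ERbeta2 of plate 02. With corrected members it held 17 clones, at a mean of -0.004 and a camera adjusted p of 0.989. The mean of the activin list was 0.06 without replicate 5, on which activin BA (02a08) was at 3.47, and 0.00 ± 0.04 over its 10 clones outside plates 02 and 04.

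Among metabolic lists, lipid and cholesterol metabolism (51 clones, mean -0.01 ± 0.06, adjusted p = 0.984) had 1 higher and 2 lower calls (2 and 6 adjusted over the list alone). They were intestinal fatty acid-binding protein, apoeb (apolipoprotein E, a lipid carrier, 02n16) at -0.53 ± 0.22 and fads2 (a fatty acid desaturase, 02i17) at -0.47 ± 0.21. Both lower clones lie on plate 02 and stood at -0.18 and -0.12 with each plate centered. The mean of the lipid list was then 0.03. Over its 42 clones outside plates 02 and 04 it was 0.07 ± 0.07, against -0.35 on them. The mitochondrial respiratory chain (94 clones, mean 0.04 ± 0.04, adjusted p = 0.10) had 1 higher call, ubiquinol-cytochrome c reductase, and with corrected members its adjusted p was 0.0432, within a range of 0.0432 to 0.827. Chaperones and oxidative stress (92 clones, mean 0.00 ± 0.03, adjusted p = 0.62) had 1 lower call, hsp90b, and ubiquitin and proteasome (96 clones, mean 0.03 ± 0.05, adjusted p = 0.297) also had 1, uchL1. Drug-metabolizing enzymes (27 clones, mean 0.03 ± 0.06, adjusted p = 0.457) had 0 calls, with a glutathione S-transferase (39p17) at 0.29 ± 0.21.

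Of the other lists, cell proliferation (8 clones, mean -0.01 ± 0.13, adjusted p = 0.676) had 1 lower call, cdc23 (a subunit of the anaphase-promoting complex, 02g14) at -0.50 ± 0.26, its fadrozole channel above background on 1 of 5 arrays. With its members corrected, 1 clone of the proliferation list was left, too few for the list test. Myelin and oligodendrocyte markers (26 clones, mean 0.03 ± 0.09, adjusted p = 0.62), immediate early genes (6 clones, mean -0.01 ± 0.10, adjusted p = 0.804) and the thyroid axis (8 clones, mean 0.06 ± 0.11, adjusted p = 0.643) had 0 calls. Among markers of other cells, blood (15 clones, mean -0.20 ± 0.32, adjusted p = 0.0739), immune cells and microglia (80 clones, mean 0.03 ± 0.05, adjusted p = 0.297) and muscle (149 clones, mean 0.00 ± 0.04, adjusted p = 0.731) had 0 calls. The 12 hemoglobin clones averaged -0.26 ± 0.40 and were below 0 on 3 of 5 arrays. The blood list, none of whose clones lay on plates 02 and 04, passed in 7 of 25 alternatives, with a mean of -0.23 and an adjusted p of 0.0186 with each plate centered, 0.0153 without the 2 plates and 0.0338 with corrected members. Without replicates 1 to 5 in turn it was 0.0246, 0.0463, 0.228, 0.0192 and 0.477, the mean being -0.11 without replicate 3 and -0.12 without replicate 5, and with an estimated correlation it was 0.649, or 0.79 with plates centered as well, within a range of 0.00474 to 0.79. The mean and the camera direction differed in sign for the chaperone, proliferation and muscle lists, and the mean and the median for these and the lipid list.

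Brain aromatase, the target of fadrozole, was measured by 3 clones. One (03k22) was at 0.29 ± 0.24 with an adjusted p of 0.203, above 0 on 4 of 5 arrays, with both channels above background on 5 of 5 arrays. The others (03n04 and 03p04) were at -0.03 ± 0.13 and -0.02 ± 0.18, but their fadrozole channel stood above background on 1 of 5 arrays each, so that these ratios rest largely on background. The estrogen receptors esr1 (02e13), ER beta1 (02c12) and ERbeta2 (02f15) were at -0.21 ± 0.33, -0.06 ± 0.07 and 0.07 ± 0.20. The androgen receptor (03m04) did not stand above background in the fadrozole channel on any array. Its ratio of -0.09 ± 0.21, below 0 on 4 of 5 arrays, therefore rests largely on background and does not show a difference. The GnRH peptides sGnRH (02a17) and cGnRH-II (02d17 and 02g15) were at -0.10 ± 0.27, -0.07 ± 0.19 and -0.31 ± 0.29, and 4 GnRH receptor clones between -0.01 and 0.22. GTH-II (a gonadotropin subunit, 02g17) was at -0.38 ± 0.32, the glutamate decarboxylases GAD3, GAD67 and GAD65 at -0.10 ± 0.21, -0.03 ± 0.08 and 0.00 ± 0.16, and tyrosine hydroxylase (TH, 02f17) at -0.22 ± 0.14. None of these passed the test, and the fadrozole channel of ER beta1 and the 4 GnRH receptor clones also stood above background on 1 of 5 arrays each. The clones of estrogen receptors, GnRH peptides, GTH-II, glutamate decarboxylases and tyrosine hydroxylase lie on plate 02, and with each plate centered esr1 stood at 0.14, ER beta1 at 0.28, ERbeta2 at 0.42, GTH-II at -0.03, sGnRH at 0.25, cGnRH-II at 0.28 and 0.04, GAD3 at 0.25, GAD67 at 0.32, GAD65 at 0.35 and TH at 0.13. ERbeta2, the androgen receptor, GnRH-Rb2 (03m02) and both low aromatase clones also changed sign under at least 1 other way of scaling the arrays. Centering moves all clones of a plate alike, while the median on plates 02 and 04 was -0.15 among the dimmest and -0.42 among the brightest. ER beta1, ERbeta2 and GAD67 had a log2 brightness of 7.07, 7.04 and 7.26, against a plate 02 median of 8.15. Centering may raise such dim clones too far, so that their centered values do not show a rise.

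Isotocin and secretogranin were each measured by several clones. Beside the called isotocin clone 02e11, 5 other clones lay between -0.19 and -0.06, and beside the called secretogranin II clone 02j04, 8 other secretogranin clones lay between -0.40 and 0.06. Of the uncalled clones of both that were below 0, 3 of isotocin (02j22, 02k01 and 02e01) and 3 of secretogranin (02e10, 02e09 and 02m19), all on plate 02, were above 0 with each plate centered. Neuropeptide Y was at -0.43 ± 0.38 (02h16, which stood at -0.08 with each plate centered) and -0.24 ± 0.20 (20m18). A further neuropeptide Y clone (61g06) did not stand above background in the fadrozole channel on any array. GFAP, an astroglial filament, was at 0.12 ± 0.14 (03p15), -0.04 ± 0.21 (03g13) and -0.06 ± 0.25 (02b01), the last at 0.29 with each plate centered and the others above background in the fadrozole channel on 1 of 5 arrays each. The limit of centering for dim clones, given above, applies to the centered values of these isotocin clones, of secretogranin 02m19 and of GFAP 02b01 too. The secretogranin clones 02e10 and 02e09 had a log2 brightness of 9.36 and 8.72, above the plate 02 median of 8.15. With each plate centered they stood at 0.08 and 0.26 and were not called. Activin BA (02a08) was at 1.12 ± 1.44 and activin BB (02g03) at 0.24 ± 0.76, and of 7 somatostatin and somatostatin receptor clones the highest was preprosomatostatin-14 (03k03) at 0.82 ± 1.10, none of them past the test. No clone matched vasotocin.

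All 5 arrays carried the same dye orientation and 1 control pool, so that dye and treatment cannot be told apart and the test leaves out the spread among control fish. Without replicate 1, 2 or 3 limma called 1, 0 and 0 clones (979, 995 and 997 at an unadjusted p under 0.05), against 174 without replicate 4 and 100 without replicate 5, and with background left in place or plainly subtracted it called 0 (1187 and 1042).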

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

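The tests of place on the slide, of spot brightness, and of source plates, repeated clones and gene families in the neuronal list were chosen only after the result was seen, as were the alternatives with plates centered or left out.

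Of the 130 clones called lower, 127 lie on source plates 02 and 04. The tables argue against place on the slide, since plate 03, printed between them, had a median of -0.040 ± 0.039 (SD over 5 arrays), and against spot brightness alone, since clones of other plates matched on brightness had a median of 0.029 ± 0.021 against -0.27 on the 2 plates, although within those plates the median fell with brightness, from -0.15 among the dimmest to -0.30 in the middle and -0.42 among the brightest. For 30 genes with clones on and off these plates, the tables also argue against lower transcript levels as the whole account. Clones of these genes on other plates averaged -0.068 ± 0.026 against -0.36, although that smaller value lies below 0 itself. The difference between clones of the same gene, -0.29 ± 0.15 and negative for 28 of 30 genes, goes with a property of the spotted source plate. Plate 04 holds 0 clones with a gene description. The comparisons by gene therefore bear on plate 02 and leave the 33 lower calls of plate 04 untested. What that property is was not tested, and a small decrease of these transcripts after fadrozole stays open.

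The neuronal cytoskeleton and synapse list was lower on all 5 arrays with a mean of -0.11 ± 0.02, its adjusted p being 0.0527 with plates centered and an estimated correlation. The 2 source plates account for a part of it, since its 14 clones there averaged -0.42 and held 8 of its 9 calls. They do not account for it alone. Without them the mean was -0.07 ± 0.02, with a camera p of 4.17e-07 at the preset correlation and an adjusted p of 0.0364 with an estimated correlation. Repeated clones with the same description do not account for it alone. With those averaged and plates centered, its camera p at the preset correlation was 0.000437, at a mean of -0.067 over 68 gene names. Clones of 1 gene or family with differing descriptions stayed apart there, so that redundant clones are not excluded. Outside the plates, the 90 clones of calmodulin, tubulin, SNAP-25, stathmin and synuclein averaged -0.097 and the 35 other clones -0.0025 ± 0.069. The difference was -0.095 ± 0.076 and below 0 on 5 of 5 arrays. Stathmin itself averaged -0.05 ± 0.13 over 10 clones, below 0 on 4 of 5 arrays. These values go with a fall of a few gene families, stathmin less clearly than the others. The families were picked after the values were seen, so that the split cannot settle this. A dye preference of the clones of the list cannot be told apart from the treatment, since 0 arrays have the opposite dye orientation. A decrease of transcripts of these families after fadrozole is a hypothesis beside it.

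Turning the sign of some arrays gives 16 splits, too few for a share under 0.05. For the number of clones called, 1 of 16 splits reached the real value of 164, and the highest of the others was 0. For the number of lists called, 2 of 16 splits reached the real value of 6, and the highest of the others was 7, with the sign of array 4 turned.

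Among 133 series of 5 arrays, 8 had 1 array far from the others, where 6.65 would by chance. EPD-II (02m23) was at -0.44 on array 4, against -0.69 to -0.63 on the others. The clone 02p05 was at -0.23 on array 4, against -0.61 to -0.55. On array 3, cdc23 (02g14) was at -0.97, against -0.42 to -0.33, and isotocin (03f07) at 0.051, against -0.13 to -0.08. On array 2, GnRH-Ra1 (03o01) was at 0.87, against -0.18 to 0.00. On array 5, ferritin L (35j18) was at 0.82, against 0.17 to 0.36, and [Pro2]somatostatin-14 (03n02) at 1.15, against 0.01 to 0.23. The mean of the cell proliferation list, with its members as first written, was 0.21 on array 5, against -0.11 to -0.03.

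The 200 PCR control spots, which the comparison leaves out, had a median log2 ratio of 0.64, above the 0.03 to 0.13 of the 336 empty spots, and ranged from 0.13 on array 3 to 3.07 on array 5.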

How the results depend on the processing

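Plate centering, leaving out plates 02 and 04, the quantification day, corrected lists and averaged clones were chosen after seeing the data. The number of clones called in limma (164, 34 higher, 130 lower, 58 at least 1.5-fold, with 36 named clones called) was 0 in all, 0 higher, 0 lower, 0 at least 1.5-fold and 0 named with background not subtracted, with plain background subtraction, with the authors' values, with a minimum fold of 1.2, with each source plate centered and without plates 02 and 04 (1187, 1042, 1124, 215, 910 and 741 clones at an unadjusted p under 0.05). A plain one-sample test called 0 (968 at an unadjusted p under 0.05), scale normalization 93 (16 higher, 77 lower), replicate spots kept apart 401 (160 higher, 241 lower), and the stricter filter, with 1370 clones tested, 314 (193 higher, 30 at least 1.5-fold, 1 at least 2-fold, 22 named). Leaving out 1 array gave 0 to 174 calls, 0 to 21 higher, 0 to 153 lower, 0 to 90 at least 1.5-fold, 0 at least 2-fold and 0 to 26 named, with 1, 0, 0, 174 and 100 calls without replicates 1 to 5. Instead of 6, the number of lists called was 1 with an estimated correlation, 3 with plates centered (2 of the 6, with blood added), 2 without plates 02 and 04 (1 of the 6, with blood added), 1 with clones averaged and plates centered, 0 with plates centered and an estimated correlation, 3 with plates centered and corrected lists (2 of the 6), and 1 without the plates and an estimated correlation, and 5 to 7 with 1 array left out. The pituitary hormone list, -0.22 as reported, reversed to 0.032 with plates centered, with that and an estimated correlation, and with that and clones averaged, and to 0.025 with plates centered and corrected lists. The plate alternatives remove the plate medians and the stricter filter tests fewer clones, but the cause of these changes was not tested. With the stricter filter, 515 of 1370 clones had an unadjusted p under 0.05 and 80 of the 314 calls were among the 164. Its calls were 193 higher and 121 lower, against 34 higher and 130 lower as reported. Print-tip loess, median centering, no filter, ignored spots kept, the intensity trend, array weights and the quantification day gave 131 to 211 calls. Of the values of lists, 471 kept their direction and side of the threshold, 46 lost their call, 10 gained one, 54 changed the direction of the list test without a call on either side and 4 reversed. For named clones, by the sign of the value, these were 1565, 366, 19, 81 and 0. An alternative foreground measure and a scan day block were not run, since the files give 1 measure and 1 scan day. The minimum fold, replicate spots kept apart, the plain test and the quantification day give no list value. The fadrozole channel, above background at 22.7% to 64.8% of the spots, limits what could be called.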

Other observations

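Ependymin, a secreted glycoprotein of the fish brain, averaged -0.45 over 17 clones on plates 02 and 04 and -0.15 over 16 clones on other plates. Apolipoprotein E averaged -0.34 over 8 clones on the 2 plates and -0.06 over 9 clones elsewhere, and creatine kinase B, an enzyme of energy storage, -0.23 over 6 clones and 0.03 over 6. For proteolipid protein, a myelin protein, the values were -0.25 for 1 clone and 0.03 over 5. Reticulon 1 and neurogranin were the genes whose clones on the 2 plates lay above the others, with 0.05 against -0.02 and 0.05 against -0.25.

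Of 8099 clones, 2 had a log2 ratio above 1 on both array 2 and array 5, a threshold chosen after the values were seen. Activin BA (02a08) was at 1.45 and 3.47 on those arrays and preprosomatostatin-14 (03k03) at 1.49 and 2.22. On the same arrays the PCR control spots had medians of 2.08 and 3.07, and on arrays 1, 3 and 4 of 0.45, 0.13 and 0.64.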
